A study of Mus musculus with 32 samples.

How the data were processed

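RNA described by the labels as ribosome-associated was sequenced in pairs of reads from neuron populations of the mouse cortex and hippocampus, in 32 libraries that the titles and tissue labels place in 8 groups of 4. Per the labels' protocols, RNA was purified with the RNeasy Plus Micro kit and libraries were made from 50 ng of RNA with a TruSeq stranded kit that selects polyadenylated RNA. The genotype of every library is labelled wild type. The genome build GRCm38 and the tools FastQC, Picard, SAMtools and featureCounts are named per the submitters' processing notes, with no role, order or version. The aligner, the annotation behind the features and the counting mode are not given in the sources used here. The use of strand in counting is not stated either, so values of overlapping or antisense features and of near-identical copies are uncertain.

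The deposited values are expected counts, that is read counts per feature that need not be whole, in 1 table of 56459 features with 1 column per library. Of the values above 0, 20.1% were whole within 1e-06. Low values piled up at multiples of 2, so both mates of a read pair appear to add to a count, and a value then stands for about 2 reads per fragment. The table also holds 12 columns of per-sample values whose names match no sample of these labels. They were not used in any step. A deposited length per feature was used only for the medians it gives in a results table, and a column of small codes with no stated meaning was not used.

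The features carry identifiers of the form GSMG plus digits. The files do not pair them with gene names, and 0 of them occurred in the reference tables used here. Gene names were therefore not assigned, and at most 2 features that were higher and 2 that were lower are printed per comparison. For the same reason the 25 gene lists with 365 genes that had been fixed before the data were examined (classes of neurons, layers, hippocampal fields, glia, vessels, ion channels, receptors, adhesion and splicing factors) could not be tested, the driver and class genes could not be looked up, and the shares of counts from other cell types could not be measured. The rows were not analysed as parts of genes, since no source used here says which features belong to 1 gene, so the use of transcript isoforms, which the study's title is about, was not tested.

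The expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr with the groups as given, which left 24555 of 56459 (43.5%) holding nearly all counts. Another 15646 features were at 0 in every library. Libraries were scaled by TMM, and a robust quasi-likelihood model with 1 coefficient per group was fitted to all 32 libraries, with 24 residual degrees of freedom. The common biological coefficient of variation was 0.253. Each of 10 contrasts was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment, and a feature was called at an adjusted p under 0.05 and at least 2-fold. The same test was run for the 28 pairs of groups. A standard error of a log2 fold change was taken as its size over the square root of F. CPM values are TMM-normalised, given as mean ± SD over libraries. Features named in the text were those with the 2 largest positive and 2 largest negative log2 fold changes among called features with a mean of at least 5 CPM in a group of the higher side and no overlap between the libraries of both sides. For the test of the difference between regional effects the overlap condition was left out. This is the rule fixed before the data were examined, shortened to 2 features each way and without its exclusion of identifiers, which would have left no feature.

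On simulated counts with changed features of known size in a step of 23602 features, the CamK hippocampus against CamK cortex contrast recovered 33 of 67 features changed 1.5-fold, 52 of 67 changed 2-fold and 63 of 66 changed 4-fold, counted at an adjusted p under 0.05, with 11 of 23402 unchanged features passing. For the difference between the regional effects these numbers were 19 of 67, 41 of 67 and 63 of 66, with 7 unchanged features passing. With no change simulated between Scnn and CamK cortex, 0 of 23602 features passed in edgeR. Changed features were drawn only from those with a mean over 1 CPM, and the 2-fold threshold of the calls was not applied.

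Principal components, Spearman correlations and distances between libraries used log2 CPM with a prior count of 2. Library measures were compared in 6 contrasts by exact permutation tests, two-sided, of the difference in means, with Benjamini-Hochberg adjustment over 18 tests, which were chosen after the data were seen. The smallest p these can give is 0.0286 for 4 libraries against 4 and 0.00202 for 4 against 8. The 6 tests of the pair of abundant features are not used, because the pair was chosen from the same libraries. For the number of features at 1 CPM or more the adjusted p was 0.00727 for VIP and for SST against CamK and Grik hippocampus, 0.0515 for Scnn against CamK, 0.726 for Grik against CamK, and 0.205 and 0.258 for region in CamK and SST. For the TMM factor it was 0.00727, 0.0121, 0.0515, 0.0856, 0.158 and 1 in that order. No replicate pair agreed within sampling noise. The chi-square per degree of freedom of fragment counts within groups ran from 13.3 to 328, so all 32 libraries were kept as separate replicates. Nothing in the labels says that replicates come from separate animals, and p-values then measure only the spread between these libraries.

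Alternatives fixed before the data were examined were DESeq2 1.42.0 with its Wald test, DESeq2 size factors in the edgeR fit, no filter on low counts, a filter of 1 CPM in at least 4 libraries, a fit of only the groups compared, the replicate number as a block, no fold threshold, and leaving out each replicate in turn. Alternatives added after seeing the data were the analysis of 0.5 of each value, leaving out the 10 most abundant features, and the use of only those groups whose titles carry no W. All alternatives of the pairwise and group-enriched counts, of the agreement of the GABAergic contrasts and of that of Scnn with VIP were also added then. The labels give no batch, but the titles fall into 2 series: CamK, Scnn, PV and SST cortex are numbered plainly, while VIP cortex and all hippocampal groups carry a W before the number. What the W stands for is not stated.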

Results

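Ribosome-associated RNA was profiled in genetically defined neuron populations of the mouse forebrain, to map what transcripts each population engages with ribosomes. Cortical libraries came from the CamK, Scnn, PV, SST and VIP populations and hippocampal libraries from the CamK, Grik and SST populations, each with 4 replicates. From knowledge of the field, and not from the labels, CamK, Scnn and Grik are taken as glutamatergic (excitatory) populations, Scnn as enriched in layer 4 of the cortex and Grik as enriched in area CA3 of the hippocampus. PV, SST and VIP are taken as classes of GABAergic (inhibitory) interneurons marked by parvalbumin, somatostatin and vasoactive intestinal peptide. Because the features carry no gene names, these identities could not be checked on marker genes, and the populations are described by numbers of features and by a few feature identifiers. Deposited counts summed to between 100158438 and 114153919 per library, except SST hippocampus replicate 1 at 186505391.

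Every population had its own ribosome-associated profile. Each of the 32 libraries was closest to a library of its own group, with Spearman correlations across features of 0.974 to 0.987 within groups and 0.901 to 0.973 between groups. The first principal component (29.5% of the variance) set the CamK and Grik libraries, with group means of -125 to -95.8, apart from the PV, SST and VIP libraries, with means of 49.6 to 118. Scnn cortex lay between them at 16 ± 20.1 (SD, n = 4). The second component (16.6%) set Scnn cortex (-104 ± 14.1) and VIP cortex (-95.7 ± 10.4) apart from the PV and SST libraries (means of 66.3 to 75). A large part of the features was nonetheless shared, since 11560 of the 24555 tested (47.1%) reached 1 CPM in all 32 libraries. At the same time 17943 (73.1%) differed in at least 1 of the 28 pairs of groups.

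**Figure D1:**
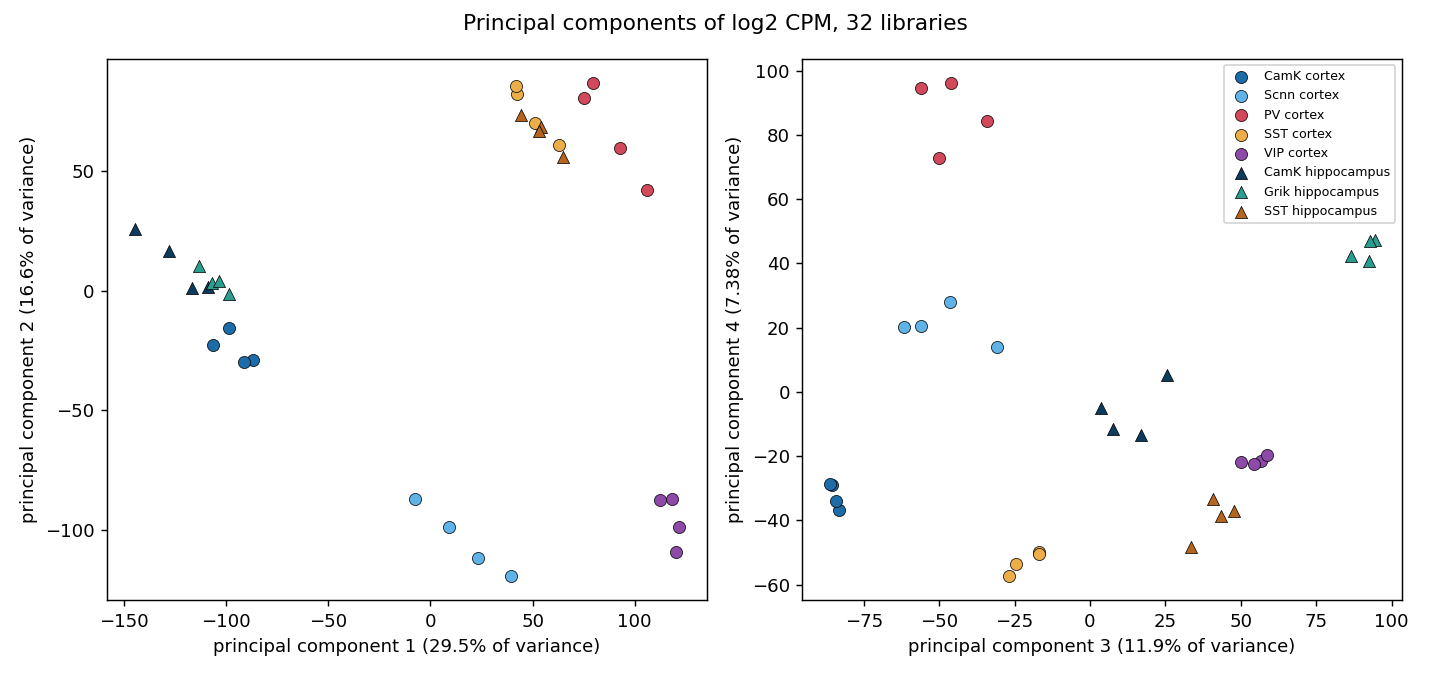
Principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM over 24555 features, 1 point per library, coloured by group, with circles for cortex and triangles for hippocampus. CamK and Grik libraries lie at the left of component 1, with group means of -125 to -95.8, and PV, SST and VIP libraries at the right, with means of 49.6 to 118.

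SST neurons of cortex and hippocampus were the most alike of the 28 pairs, with 1833 features called. CamK and Grik hippocampus followed with 3288, CamK cortex and hippocampus with 3411, and PV and SST cortex with 3723. Grik hippocampus and VIP cortex gave the most calls, 8746, of which 6197 were higher in VIP. That rank depended on features of low abundance, since under the filter of 1 CPM in at least 4 libraries this pair had 5594 calls and Grik hippocampus and PV cortex the most, 6154. By root mean square difference CamK hippocampus and VIP cortex were the furthest apart (1.78, against 1.70 for Grik and VIP). Average-linkage grouping of the group means first joined both SST groups, at a root mean square difference of 0.79 on the log2 scale. It then joined CamK and Grik hippocampus (0.96), PV cortex with the SST groups (1.07), CamK cortex with the hippocampal CamK and Grik groups (1.14), and Scnn with VIP cortex (1.19), although Scnn was about as close to CamK cortex (1.18). Scnn and VIP then joined the PV and SST groups (1.36), apart from CamK and Grik. VIP and PV cortex held the most features higher than in every other group, 416 and 405. Grik hippocampus held 254, Scnn cortex 164, CamK cortex 136, SST cortex 89, CamK hippocampus 87 and SST hippocampus 69. PV cortex and Grik hippocampus also had the most features lower than in every other group, 554 and 442, while VIP cortex had 50 and SST cortex 36. These counts depend on which groups were sampled. SST and CamK were sampled in both regions, so each of their groups must also differ from its counterpart in the other region, which the remaining groups lack.

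GABAergic and glutamatergic populations of the cortex differed in 5968 features (24.3% of those tested), with 3188 higher in the mean of PV, SST and VIP and 2780 higher in the mean of CamK and Scnn. The changes were large: 550 features were at least 8-fold higher and 447 at least 8-fold lower in the GABAergic populations. GSMG0022957 stood at 220.4 ± 31.1 CPM over the 12 GABAergic libraries and 4.1 ± 3.74 CPM over the 8 glutamatergic ones, a log2 fold change of 6.47 (SE 0.22, edgeR adjusted p = 1.33e-19). GSMG0024189 differed by 6.30 (SE 0.25, adjusted p = 1.74e-19). In the other direction GSMG0037152 differed by -5.74 (SE 0.40, adjusted p = 1.04e-12), with 16.2 ± 2.93 CPM in Scnn and 0.61 ± 0.17 CPM in CamK, so its difference lay mostly in Scnn. GSMG0025138 differed by -5.67 (SE 0.49, adjusted p = 1.56e-11), again with more in Scnn (5.53 ± 1.24 CPM) than in CamK (1.1 ± 0.34 CPM). Within the groups whose titles carry no W (PV and SST against CamK and Scnn) 6053 features were called, 2679 higher and 3374 lower, so the larger side changed when VIP was left out. It also changed among called features with a mean of at least 1 CPM over all libraries, of which 1496 were higher and 1616 lower (48.1% higher). Under the filter of 1 CPM in at least 4 libraries it did not change, with 2108 higher and 1906 lower (52.5% higher).

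**Figure D2:**
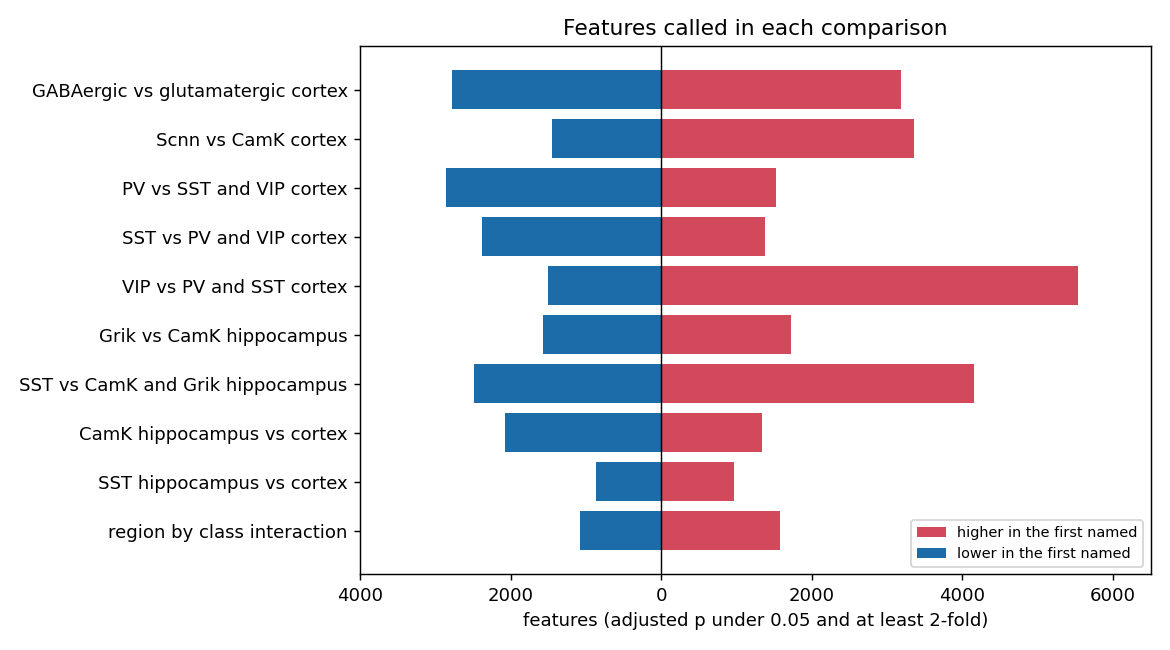
Number of features called (adjusted p under 0.05 and at least 2-fold) in each of the 10 comparisons, with features higher in the group named first to the right and lower ones to the left of 0. VIP against PV and SST cortex has the longest bar, with 5542 features higher, and SST hippocampus against cortex the fewest calls, 1833. For the last bar pair, right means a higher hippocampus-to-cortex change in SST than in CamK.

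Between the glutamatergic cortical populations, Scnn differed from CamK in 4811 features, and 3353 of these (69.7%) were higher in Scnn. The excess of higher features was smaller among those more abundant over all libraries. A feature found in Scnn alone passes such a cut less easily than one found in most groups, and likewise in the other comparisons. Among called features with a mean of at least 1 CPM over all libraries, 1142 were higher and 925 lower (55.2% higher). GSMG0033684 was at 12.1 ± 1.55 CPM in Scnn and 0.24 ± 0.06 CPM in CamK (log2 fold change 5.63, SE 0.41, edgeR adjusted p = 1.34e-12). GSMG0018104 had the largest estimate, 6.71 (SE 2, adjusted p = 0.00901), but its 4 Scnn libraries ranged from 0.36 to 29.3 CPM, and without Scnn replicate 2 the estimate was 4.38 and the call was lost (adjusted p = 0.0986). GSMG0000011 (log2 fold change -4.03, SE 0.40, adjusted p = 1.1e-09) and GSMG0019139 (-3.29, SE 0.26, adjusted p = 9.12e-12) were lower in Scnn. Scnn libraries also carried far more counts in a pair of abundant features, GSMG0038934 and GSMG0023431, singled out after their values were seen. Their joint share was 6.72% ± 4.5 in Scnn and 0.25% ± 0.08 in CamK (n = 4 each), given without a test because the pair was chosen from these libraries. The excess also needed the fold threshold, since without it 4754 of 10234 features (46.5%) were higher in Scnn. Under the filter of 1 CPM in at least 4 libraries 2970 features were called and 1921 of them (64.7%) were higher.

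PV cortex differed from the mean of SST and VIP cortex in 4388 features, 1527 higher and 2861 lower in PV. GSMG0005550 (33.2 ± 5.7 CPM in PV, 0.47 ± 0.3 CPM over SST and VIP, log2 fold change 6.18, SE 0.31, edgeR adjusted p = 8.23e-17) and GSMG0038980 (5.92, SE 0.40, adjusted p = 1.26e-12) marked PV. GSMG0003666 was nearly lacking in PV (0.49 ± 0.16 CPM) but at 638.2 ± 84.3 CPM in VIP and 21.2 ± 4.22 CPM in SST (log2 fold change -7.87, SE 0.45, adjusted p = 5.53e-14). GSMG0038910 had the same order, with 1.44 ± 0.3 CPM in PV, 125.2 ± 14.7 CPM in SST and 794.7 ± 80.4 CPM in VIP (-7.78, SE 0.33, adjusted p = 6.14e-17). Within the plainly numbered titles, PV against SST alone gave 3723 calls, 1493 higher and 2230 lower in PV.

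SST cortex differed from the mean of PV and VIP cortex in 3765 features, 1375 higher and 2390 lower in SST. GSMG0023525 stood at 772.8 ± 207 CPM in SST cortex against 10.3 ± 6.29 CPM over PV and VIP (log2 fold change 6.40, SE 0.40, edgeR adjusted p = 1.65e-12), and GSMG0015234 at 15.1 ± 2.19 CPM against 0.15 ± 0.12 CPM (6.75, SE 0.46, adjusted p = 8.3e-13). GSMG0004899 (-4.59, SE 0.50, adjusted p = 2.78e-08) and GSMG0031130 (-4.46, SE 0.31, adjusted p = 2.87e-13) were lower in SST. The balance of the calls depended on VIP and on the fold threshold, without which 5364 of 9696 features (55.3%) were higher in SST. Against PV alone, within the plainly numbered titles, 2230 of 3723 features (59.9%) were higher in SST, against 36.5% in the comparison with both. For GSMG0004899 the log2 difference against PV alone was -1.95 (edgeR adjusted p = 0.00297).

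VIP cortex stood furthest from the other interneurons, with 7049 features (28.7% of those tested) differing from the mean of PV and SST. Of these, 5542 (78.6%) were higher in VIP and 1507 lower, and 1278 of the former were at least 8-fold higher. The share of higher features was 65.2% among called features with a mean of at least 1 CPM, and 55.2% (7998 of 14490) without the fold threshold. GSMG0003738 reached 2749 ± 1080 CPM in VIP against 5.54 ± 2.46 CPM in PV and SST (log2 fold change 9.05, SE 0.39, edgeR adjusted p = 3.35e-16). GSMG0021962, at 6.52 ± 1.18 CPM in VIP, had only 8 counts in the 8 PV and SST libraries together (9.44, SE 0.71, adjusted p = 4.25e-12). GSMG0022700 (-6.12, SE 0.41, adjusted p = 1.42e-12) and GSMG0010975 (-5.82, SE 0.28, adjusted p = 8.8e-16) were much lower in VIP, at 1.32 ± 0.61 and 2.93 ± 1.35 CPM. More features reached 1 CPM in VIP libraries, 15065 to 15483, than in any library of the other groups, the highest of which was Scnn replicate 2 at 14808 (VIP against PV and SST, exact permutation test, two-sided p = 0.00202, the smallest possible, adjusted p = 0.00727). The joint share of the same pair of abundant features was 5.04% ± 1.31 in VIP (n = 4) and 1.4% over PV and SST (n = 8), again given without a test. Under the filter of 1 CPM in at least 4 libraries 4197 features were called, 3077 of them higher (73.3%). VIP cortex carries a W in its titles and PV and SST cortex do not, so the population and the title series cannot be told apart in this comparison.

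**Figure D3:**
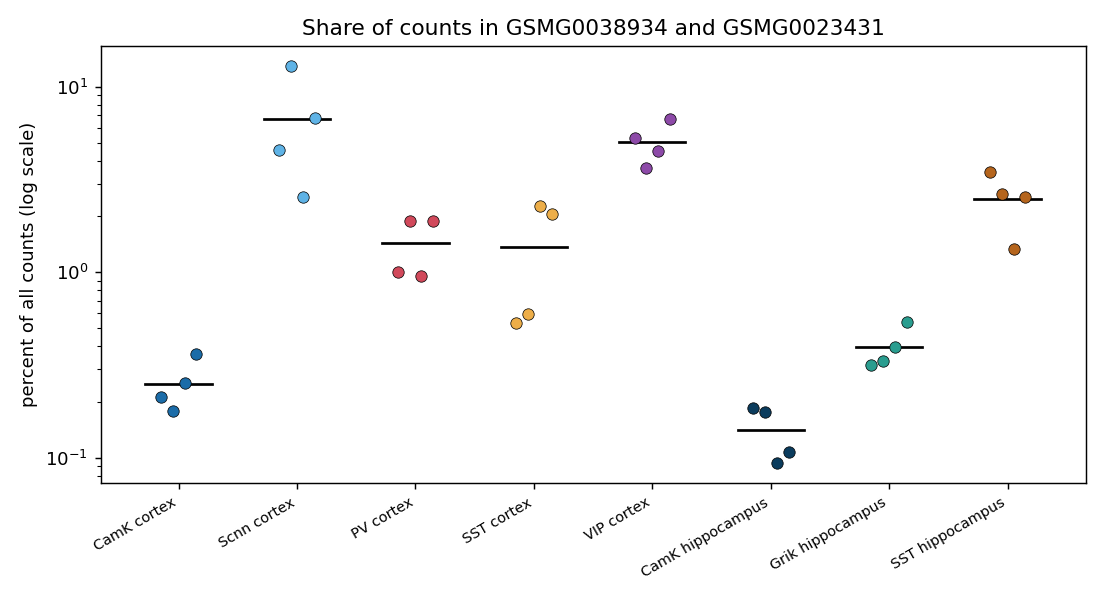
Joint share of all deposited counts in the pair of abundant features, as a percentage on a log axis, 1 point per library with the group mean as a bar. Scnn cortex (mean 6.72%) and VIP cortex (5.04%) lie highest and CamK hippocampus (0.14%) lowest.

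In the hippocampus, Grik differed from CamK in 3288 features (13.4% of those tested), split almost evenly into 1717 higher and 1571 lower in Grik. GSMG0001554 separated them most, at 24.2 ± 2.45 CPM in Grik and 0.15 ± 0.04 CPM in CamK (log2 fold change 7.29, SE 0.41, edgeR adjusted p = 2.1e-15), and it stayed below 0.4 CPM on average in each of the other groups. GSMG0003738, named above for VIP cortex, was also higher in Grik (15.7 ± 6.98 CPM) than in CamK (0.49 ± 0.22 CPM), by 4.99 (SE 0.50, adjusted p = 1.4e-08). GSMG0018752 (-6.23, SE 0.62, adjusted p = 1.25e-09) and GSMG0005653 (-6.02, SE 0.55, adjusted p = 2.37e-10) were lower in Grik. Without CamK replicate 4 the larger side turned, with 1437 of 2971 features (48.4%) higher in Grik. Both groups belong to the W title series.

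SST interneurons of the hippocampus differed from the mean of CamK and Grik hippocampus in 6645 features, 4157 higher (62.6%) and 2488 lower in SST. The share of higher features was 52.0% among called features with a mean of at least 1 CPM over all libraries (1791 higher, 1652 lower). It was 56.9% under the filter of 1 CPM in at least 4 libraries and 54.2% without the fold threshold. GSMG0010975 stood at 289.6 ± 54.2 CPM in SST and 0.41 ± 0.15 CPM in CamK and Grik (log2 fold change 9.45, SE 0.26, edgeR adjusted p = 1.54e-21), and GSMG0028346 at 9.02 ± 1.61 CPM against 0.06 ± 0.07 CPM (9.59, SE 0.42, adjusted p = 4.48e-18). GSMG0033068 fell from 1078 ± 290 CPM in CamK and Grik to 40 ± 11.9 CPM in SST (-4.72, SE 0.23, adjusted p = 2.14e-16), and GSMG0005599 differed by -4.91 (SE 0.26, adjusted p = 4.75e-17). The contrast ran parallel to the one in the cortex, with which it shares no library. The log2 fold changes of GABAergic against glutamatergic cortex and of SST against CamK and Grik hippocampus had a Pearson correlation of 0.58 across 24555 features, which are not independent replicates (Spearman 0.60). The Pearson value was 0.39 without a filter on low counts and 0.67 under the stricter filter. Features higher in both numbered 1842, where independent lists of these lengths would share 539.7, and features lower in both 1371, against 281.7. Features called in opposite directions numbered 228, against 793.7. SST and CamK each belong to both contrasts, on the same sides, so the agreement is in part that of SST against CamK in 2 regions. All these groups of the hippocampus carry the W.

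Region was compared within CamK and within SST. In CamK neurons 3411 features differed between hippocampus and cortex, 1333 higher and 2078 lower in the hippocampus. GSMG0035286 was at 21.5 ± 6.15 CPM in hippocampus and had 12 counts in the 4 cortical libraries together (log2 fold change 9.42, SE 0.78, edgeR adjusted p = 1.11e-10). GSMG0018104 was at 37.7 ± 19.1 CPM against 0.08 ± 0.08 CPM (8.85, SE 2.01, adjusted p = 0.00107). This feature varied widely within other groups, from 0.47 to 146.6 CPM in Grik hippocampus and from 3.42 to 328.6 CPM in SST hippocampus. GSMG0005879 (11.8 ± 2.82 CPM in cortex and 0.07 ± 0.01 CPM in hippocampus, -7.43, SE 0.29, adjusted p = 4.84e-19) and GSMG0000011 (-6.68, SE 0.48, adjusted p = 7.05e-13) were within CamK nearly limited to the cortex. Hippocampal groups carry the W and the cortical CamK and SST groups do not, so that region and title series cannot be told apart within either population. GSMG0043055, described under the other observations, was at 10 CPM or more in 1 of 4 CamK cortex and 3 of 4 CamK hippocampus libraries. A feature that differs with it is partly confounded with region in CamK.

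In SST neurons 1833 features differed between the regions, 963 higher and 870 lower in the hippocampus. GSMG0023525, the abundant SST cortex feature, stood at 772.8 ± 207 CPM in cortex and 10.8 ± 11.2 CPM in hippocampus (log2 fold change -6.17, SE 0.53, edgeR adjusted p = 4.18e-09). GSMG0003159 was at 25.7 ± 6.87 CPM in cortex and 0.43 ± 0.21 CPM in hippocampus (-5.90, SE 0.51, adjusted p = 2.33e-09). GSMG0000982 (5.16, SE 1.28, adjusted p = 0.00414) and GSMG0015631 (4.79, SE 0.72, adjusted p = 8.44e-06) were higher in the hippocampus. GSMG0000982 ranged from 1.12 to 9.1 CPM in the SST hippocampus libraries. It was also at 3.45 ± 0.79 CPM in VIP cortex, which carries the W, and at 0.53 ± 0.3 CPM in CamK hippocampus. The plainly numbered groups had means of at most 0.94 CPM, so region and title series cannot be told apart for it. The near-even split turned without the fold threshold, where 2486 of 5396 features (46.1%) were higher in the hippocampus. Among called features with a mean of at least 1 CPM 519 were higher and 519 lower. The larger side also turned without SST cortex replicate 1 (48.2% higher), SST cortex replicate 3 (49.9%) or SST hippocampus replicate 5 (49.5%).

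The regional differences of CamK and SST neurons overlapped only in part. Across features their log2 fold changes, which come from separate libraries, had a Pearson correlation of 0.23 (Spearman 0.20, covariance 0.36, SE of the Pearson value 0.04 by leaving out libraries). The Pearson value was 0.14 without a filter on low counts and 0.33 under the filter of 1 CPM in at least 4 libraries. Features higher in the hippocampus in both numbered 294, where independent lists would share 52.3, and features lower in both 329, against 73.6. Features called in opposite directions numbered 154, against 128.7. The regional effect itself differed between CamK and SST in 2659 features by the test of the difference, 1571 with a higher hippocampus-to-cortex change in SST and 1088 with a higher one in CamK. Of these 2659 features, 1389 were called for region in CamK and not in SST, 462 in SST and not in CamK, 154 in both with opposite directions, 119 in both with the same direction and 535 in neither. GSMG0005879, which fell from cortex to hippocampus in CamK, was in SST at 5.59 ± 0.58 CPM in cortex and 5.71 ± 1.79 CPM in hippocampus (difference of log2 changes 7.46, SE 0.35, edgeR adjusted p = 1.38e-16). GSMG0000011, which also fell in CamK, was in SST at 1.8 ± 0.16 CPM in cortex and 2.2 ± 0.36 CPM in hippocampus (6.97, SE 0.59, adjusted p = 8.97e-11). GSMG0029117 rose from 0.29 ± 0.14 to 2.45 ± 0.53 CPM from cortex to hippocampus in CamK and fell from 9.02 ± 1.38 to 0.47 ± 0.07 CPM in SST (-7.35, SE 0.59, adjusted p = 3.37e-11). GSMG0043833 rose in CamK from 0.42 ± 0.21 to 11.4 ± 1.23 CPM and was at 3.66 ± 1.01 and 1.29 ± 0.37 CPM in SST (-6.26, SE 0.46, adjusted p = 4.49e-12). A shift shared by all libraries with a W would cancel in this test of the difference.

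**Figure D4:**
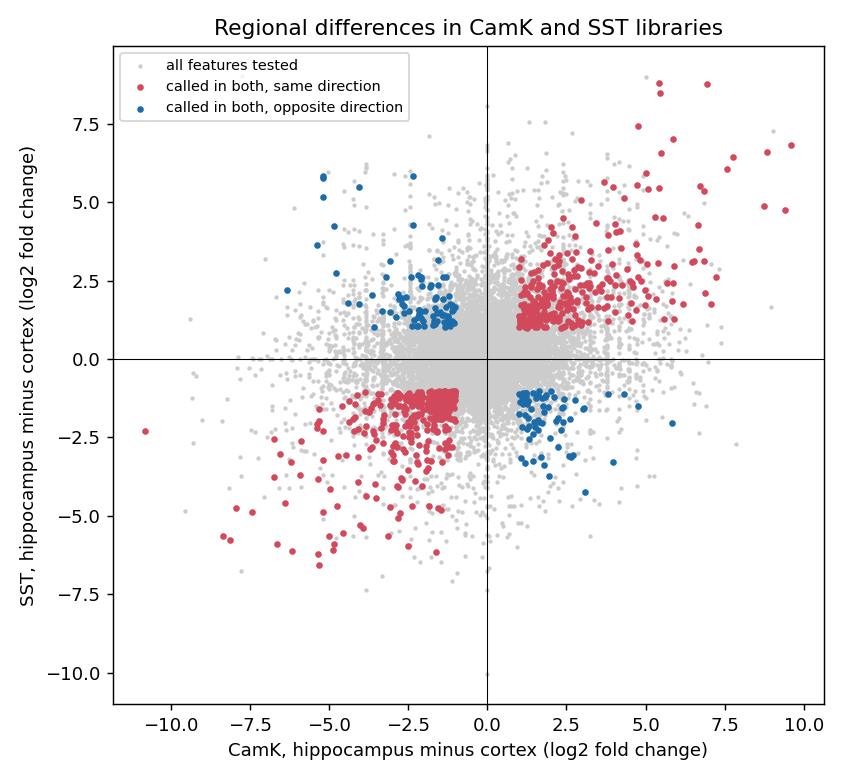
Log2 fold change between hippocampus and cortex in CamK (horizontal) and SST (vertical), 1 point per feature over 24555 features, grey for all features. Red points are the features called in both with the same direction, 294 higher and 329 lower, and blue points the 154 called in opposite directions.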

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

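The tests in this part were planned before their results were seen, except that the number of splits for comparisons of more than 2 groups was raised from 40 to 100 after the first 40 had been seen. Each group of 4 libraries was searched for a library standing apart from the other 3, on 4 library measures and on the features named in the report, and 8 of 106 such sets held one, where chance gives about 5.3. SST hippocampus replicate 1 had the deepest library, 186505391 counts against 114153919 in the next. SST hippocampus replicate 3 had a TMM factor of 1.06 against 1.01 in the next. GSMG0018104 was at 29.3 CPM in Scnn cortex replicate 2 and 3.58 CPM in the next library of the group. GSMG0023525 was at 27.6 CPM in SST hippocampus replicate 5 and 6.33 CPM in the next, far below its 772.8 CPM in SST cortex. GSMG0000011 was at 2.04 CPM in SST cortex replicate 2 against 1.74 CPM. GSMG0022700 was lowest in SST cortex replicate 4, at 118.5 CPM against 128.1 CPM. GSMG0001554 was at 27.9 CPM in Grik hippocampus replicate 3 against 23.3 CPM, and GSMG0029117 at 3.24 CPM in CamK hippocampus replicate 3 against 2.24 CPM.

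The change from cortex to hippocampus differed between CamK and SST neurons in 2659 features, by the test of the difference itself. With only the 16 libraries of these groups in the fit 2664 features were called, and 2 of 100 splits of the libraries, the real one included, gave as many. The other one gave 5019. It set 7 of the 8 SST libraries against 7 of the 8 CamK libraries, so it follows the difference between these populations, a structure of the samples that such splits do not hold fixed. Such splits therefore cannot decide whether chance gave the difference between the regional effects. The share was 2 of 100, and the first 40 splits held the same 2, a share of 0.05.

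For each of the other 9 comparisons, in fits of only the groups compared, 1 split, the real one, gave as many calls. A chance division of these libraries is thus argued against. Such splits mix distinct populations, and they do not address the title series or whether replicates come from separate animals. Of the 35 splits of 4 libraries against 4, the real one gave 3856 calls for Scnn against CamK cortex (highest other 0), 2761 for Grik against CamK hippocampus (1), 3026 for CamK hippocampus against cortex (1) and 1686 for SST hippocampus against cortex (0). Of 100 splits drawn for the comparisons of more groups, the real one gave 5963 calls for GABAergic against glutamatergic cortex (1422, in a split that kept 10 of the 12 GABAergic libraries on 1 side), 4348 for PV (0), 3916 for SST (425) and 6731 for VIP (1) against the other cortical interneurons, and 5601 for SST against CamK and Grik hippocampus (0).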

How the results depend on the processing

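Alternatives on 0.5 of each value, without the 10 most abundant features and within titles without W were chosen after seeing the data, as were all alternatives of the pairwise and group-enriched counts and of the agreement of the GABAergic contrasts and of Scnn with VIP. Of 2004 results under alternatives, 27 moved, counts by more than 1.5 times or correlations by more than their SE, and 1 lost its call. No log2 fold change of a named feature changed sign. Totals do not show the balance of higher and lower calls, whose larger side turned under 11 alternatives in 5 of the 10 contrasts, and in some of the pairwise counts, not listed here. In the contrasts these were GABAergic against glutamatergic cortex without the W titles (44.3% higher), Scnn against CamK without the fold threshold (46.5%), SST against PV and VIP without the W titles (59.9%) or the fold threshold (55.3%), and Grik against CamK without CamK replicate 4 (48.4%). The others were for region in SST, without the fold threshold (46.1%), with the replicate block (49.7%), under the stricter filter (49.5%) and without SST cortex replicate 1 (48.2%), SST cortex replicate 3 (49.9%) or SST hippocampus replicate 5 (49.5%). The lost call was GSMG0018104 in Scnn against CamK cortex without Scnn replicate 2 (4.38, adjusted p = 0.0986). Without the fold threshold the calls rose, by construction, to 14424 for GABAergic against glutamatergic cortex, 10234 for Scnn against CamK, 11324 for PV, 9696 for SST and 14490 for VIP against the other interneurons, 8088 for Grik against CamK, 13210 for SST against CamK and Grik, 8723 for region in CamK, 5396 for region in SST and 5694 for their difference. The filter of 1 CPM in 4 libraries, which tests fewer features of low abundance, left 2970 calls for Scnn against CamK and 4197 for VIP. It also lowered 5 more pairwise counts by over 1.5 times: Grik hippocampus and VIP from 8746 to 5594, VIP and CamK cortex from 8701 to 5179, VIP and CamK hippocampus from 8393 to 5126, VIP and SST cortex from 5831 to 3702, and Scnn and CamK hippocampus from 6371 to 4092. DESeq2 size factors and the DESeq2 test moved no count of calls by more than 1.5 times and no share of higher calls by over 10 percentage points. The correlation of the regional changes of CamK and SST was 0.14 without a filter on low counts, 0.33 under the stricter filter and 0.28 on 0.5 of each value, and that of the GABAergic contrasts was 0.39, 0.67 and 0.63, and the cause was not tested.

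Leaving out 1 replicate at a time gave 5739 to 6165 calls for GABAergic against glutamatergic cortex, 4254 to 4733 for Scnn, 4006 to 4578 for PV, 3216 to 3845 for SST, 6533 to 7231 for VIP, 2971 to 3365 for Grik, 6207 to 6667 for SST hippocampus against CamK and Grik, 3206 to 3424 and 1580 to 1805 for region in CamK and SST, 2479 to 2667 for their difference, and 0.19 to 0.24 for the correlation of the regional changes.

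The titles reuse replicate numbers. Across all groups, equally numbered libraries deviated together weakly if at all. Of 88 correlations 4 exceeded 0.1, with a median of 0.003 and a highest value of 0.123. All 4 lay among PV, Scnn and SST cortex, which belong to the plainly numbered titles. None of 22 pairs of groups with at least 3 shared numbers had every correlation above 0.1. Of the 32 libraries, 11 correlated best with one of their own number, and the number that chance would give was not computed. With the number as a replicate block the calls were 5913 for GABAergic against glutamatergic cortex, 4640 for Scnn, 7041 for VIP and 2595 for the difference of regional changes, and no count moved by more than 1.5 times. The tests of gene lists, of other cell types and of parts of genes planned before the data were examined were not run, because the features carry no gene names. At 100158438 counts or more per library, depth limits mainly features of low abundance. In simulated data 33 of 67 changes of 1.5-fold, in features over 1 CPM, passed the adjusted p between CamK hippocampus and cortex. Small changes were thus often missed even without the 2-fold threshold of the calls.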

Other observations

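The test on features that are on or off within a group was chosen only after its result was seen, and the comparison of Scnn with VIP was chosen after the data were seen. Scnn and VIP cortex, 1 glutamatergic and 1 GABAergic population, shared many of the features that set each apart from its own class. The log2 fold changes of Scnn against CamK and of VIP against PV and SST, which share no library, had a Pearson correlation of 0.41 across features. Features higher in both numbered 2266, where independent lists would share 756.8, and features lower in both 177, against 89.5. Features called in opposite directions numbered 591, against 534.8, so the sharing lay mostly in the higher features. Under the filter of 1 CPM in at least 4 libraries 1313 features were higher in both, and the correlation was 0.32 both there and without a filter.

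Both populations also had more higher than lower features, and RNA of other cells that rises with the pair of abundant features may contribute. Within the other groups, the median feature called higher rose with the log2 share of that pair, and 69.4% (Scnn) and 69.3% (VIP) of these features had a steeper slope than the median uncalled feature. The excess of the median slope over that of uncalled features would give 21.8% of the median change for Scnn. With a group left out it gave 14.8% to 32.2%. For VIP it would give 13.4% (6.63% to 19.3%), a small part if the trend is linear. A share that follows such RNA only loosely would make these slopes too small, so RNA of other cells stays open for both. Under DESeq2 size factors higher features made up 73.7% (Scnn) and 81.6% (VIP) of calls. These factors shift the log2 fold changes by only 0.0836 and 0.0734 from TMM, so they cannot decide whether scaling plays a part. Without the 10 most abundant features the shares were 72.3% and 76.6%. TMM already limits the weight of such features in the scaling, so leaving them out could change little and decides nothing further. A difference between the populations themselves, which the design names, stays open as untested. The title series is argued against as the only source of the excess in VIP. Within the W titles, VIP cortex against SST hippocampus had 3973 features higher in VIP and 1454 lower, though region differs there too. Where W and region changed together, 963 features were higher and 870 lower in SST, and 1333 higher and 2078 lower in CamK.

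The features changed alike between hippocampus and cortex in CamK and SST, 294 higher and 329 lower, could come from the libraries with a W in their titles, which hold all hippocampal groups. VIP cortex carries the W and PV cortex does not. The gap between the medians of these sets was 0.73 on the log2 scale for VIP minus PV, against 4.04 for the regional changes. Both sets were higher in VIP, with medians of 1.71 (shared higher) and 0.979 (shared lower), against 0.231 over all features. The gap for VIP minus PV is 18.1% of the regional one, with an upper bound of 23.9% (95% bootstrap over features, which are not independent replicates). This cannot decide on the title series as the main cause of the shared changes. The regional gap was taken from features chosen by those same contrasts, and VIP and PV differ as populations as well as in the W. The part played by the series stays open. So do a regional difference common to both populations and RNA of other cells of each region in both preparations, which were not tested.

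GSMG0043055, picked after its values were seen, was at 17.5 to 75 CPM in 22 libraries and below 1 CPM in 10, while GSMG0051096 was at 1 CPM or more in those 10 and below 1 CPM in 20 of the 22. SST hippocampus replicate 5 (31.8 and 5.4 CPM) and VIP cortex replicate 3 (17.5 and 24.1 CPM) had both. The 22 were spread unevenly. They were 1 of 4 in CamK cortex, 2 in Grik and in Scnn, and 3 in CamK hippocampus, PV and SST cortex. In SST hippocampus and VIP they were 4 of 4. Any feature that differs with this on or off state is thus partly confounded with the comparisons of region and of VIP. The same holds for those of GABAergic with glutamatergic populations in cortex and hippocampus. The fit held no term for this state, and no alternative adjusted for it. In the libraries that had both, 4 features that are on together stood below their mean in the rest of the group. Their fractions of that mean were 0.35 to 0.523 in SST hippocampus replicate 5 and 0.297 to 0.473 in VIP cortex replicate 3. Material pooled from 2 kinds of animals may lower them, a hypothesis the labels give no way to check. Pooling alone would give 1 common fraction per library, and whether the fractions within a library are equal was not tested. No biological explanation was tested.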
